A study of Homo sapiens with 2 samples.

How the data were processed

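The series holds 2 single-cell RNA libraries of human peripheral blood mononuclear cells (PBMC), the lymphocytes, monocytes and dendritic cells separated from blood. Per the labels, cells for the first library were co-cultured with an endovascular device under development and cells for the second with a device already in clinical use. There was 1 library per device, so there was no replicate and no test between the devices. The duration of the co-culture and the number of donors are not given in the sources used here.

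For each library, a list of cell barcodes and a list of gene features were used. As deposited, a barcode list gives on each line the sequence that tags the transcripts of one droplet, 16 bases long, followed by a suffix. A feature list gives a gene identifier, a symbol and a feature type. Neither kind of file holds a measured value, and the matrix that links barcodes to genes was not analysed here. Per the submitters' processing notes, Seurat and the genome build GRCh38 were used. The aligner, the counting program, the annotation release, the rule by which barcodes were kept as cells, and any filter on doublets are not given in the sources used here. Per the labels' protocols, libraries were made with an Illumina TruSeq RNA kit, a kit for bulk RNA that adds no droplet barcode, whereas both lists hold droplet barcodes. The number of reads or molecules per cell is unknown here, and the number of listed barcodes depends on the unstated rule for keeping cells.

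Barcodes were counted per library, with exact 95% Poisson intervals, and their ratio was given an exact 95% binomial (Clopper-Pearson) interval. These intervals cover counting error only and not the spread between cultures. Barcodes were matched between libraries without their suffix. The number shared was compared with the product of both list lengths divided by the size of the barcode pool, for pools of 737280, 3686400 and 6794880 sequences, which are sizes of commercial droplet barcode sets and were taken from general knowledge of these kits, not from the files. A further expectation, added after the data were seen, joined the first and last 8 bases at random as often as each occurred in each library and needed no assumed pool. Pairs of barcodes at Hamming distance 1 (differing at 1 base) were counted within each library and compared with 20 random lists. On simulated data, 20 pairs of lists of 24000 barcodes were drawn from a pool of 3240000. The Poisson interval held the true expectation in 20 of the 20 pairs, and 200 planted shared barcodes were detected as an excess in 20 of 20. The planted number was larger than the whole observed overlap of 156, so the simulation does not show that a smaller excess would be detected.

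Feature identifiers were matched without version numbers to GENCODE release 29, an annotation of GRCh38 that need not be the release the submitters used. Of 38606 identifiers, 34436 (89.2%) were found there, and gene types and coordinates were taken from that release for those genes only. Against a second table that pairs identifiers with symbols, 38582 matched. Before the data were examined, 12 gene lists for immune and device responses and 14 lists of cell type markers were fixed, together with a plan for clustering and expression that applied only if a matrix was used. By the rule fixed then, their members are named only as listed or not listed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were unique barcode sequences, removal of shared or neighbouring barcodes, inexact and reverse-complemented matching, other random lists, and counting genes by symbol.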

Results

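The study set PBMC exposed to a device under development beside PBMC exposed to a clinical reference device, to compare the immune response to each. The developed-device library listed 24659 cell barcodes (exact 95% Poisson interval 24352 to 24969) and the clinical-device library listed 24202 (23898 to 24509). Expression values per cell were not analysed here. No gene, gene group or cell type is therefore reported as higher or lower with either device, and the shares of T cells, B cells, NK cells, monocytes and other PBMC are not reported.

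The first comparison concerned how many cell barcodes were kept with each device. The developed-device library held 457 more barcodes than the clinical-device library, a ratio of 1.019 (exact 95% binomial interval 1.001 to 1.037), and made up 50.5% (50.02% to 50.91%) of the 48861 barcodes of both libraries. The interval covers counting error only. With 1 library per device there was no spread between cultures to set this difference against, and no test between the devices was made. The number of cells loaded into each reaction is not given in the sources used here, so the numbers of barcodes do not measure survival or adhesion of cells.

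The second comparison concerned the genes that could be measured. The gene lists of both libraries were identical line by line, with 38606 genes each, so a gene open to measurement in one library was open to it in the other. Since the lists hold no measured value, this match says nothing on the devices or on which genes were detected. The list held 19234 of the 19951 protein-coding genes of GENCODE release 29 (96.4%) and 14448 of its 14994 long non-coding genes (96.4%). Genes for the antigen receptors of lymphocytes were complete, with 213 of 213 immunoglobulin segments and constant genes and 195 of 195 T cell receptor segments and constant genes. The 13 mitochondrial genes carrying the MT- prefix were listed, a group whose share of transcripts is commonly used to judge cell damage. The list held 0 of 1879 microRNA genes of GENCODE release 29 and 0 of its 2901 small nuclear, nucleolar and Cajal body RNA genes. Of its 60 ribosomal RNA genes, mitochondrial ones included, 0 were listed. The 4170 identifiers not found in that release had no gene type here, so they were not counted in any class. Listed shares therefore depend on the release, and an unlisted identifier does not by itself show that the gene could not be measured. Of 10191 processed pseudogenes, 12 were listed.

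All 113 genes of the 12 response lists were on this list, each under a single identifier, which does not show that any of them was detected. The 15 interferon response genes included ISG15, MX1 and IFIT1, which interferon induces. The 17 genes of the NF-kB and inflammatory cytokine list included IL1B, IL6 and TNF, which encode secreted inflammatory cytokines, and the neutrophil attractant CXCL8. The 5 inflammasome genes included NLRP3, a sensor, and CASP1, the protease that matures interleukin-1 beta. The list for macrophages and the foreign body response held 13 genes, among them CD68, MRC1, SPP1 and MMP9. For contact with blood, the 8 coagulation genes included F3, which encodes tissue factor, the initiator of clotting. For metal exposure, 7 genes were listed, among them MT2A and MT1X, which encode metal-binding metallothioneins, and SLC30A1, a zinc exporter. The other response lists were also complete, covering T cell activation (10 genes), cytotoxicity (8), antigen presentation (10), stress and dissociation (9), apoptosis (6) and oxidative stress (6).

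All 73 genes of the 14 cell type marker lists were on the gene list as well, which does not show that such cells were in either library. These covered the lymphocytes of blood, with CD3D and CD3E for T cells, MS4A1 and CD79A for B cells, KLRD1 and KLRF1 for NK cells and MZB1 for plasma cells. They also covered myeloid cells, with CD14 and LYZ for classical monocytes, FCGR3A for non-classical monocytes, CD1C for conventional and LILRA4 for plasmacytoid dendritic cells. FCGR3A was also on the NK cell list, so it does not mark these monocytes alone. Markers of cells that can remain in a PBMC preparation were listed too, namely PPBP and PF4 for platelets, HBB for erythroid cells, FCGR3B for neutrophils and CD34 for progenitors, as was PECAM1, a marker of endothelium that leukocytes and platelets also express. Near-identical pairs such as FCGR3A and FCGR3B, HBA1 and HBA2, and HSPA1A and HSPA1B were listed as separate genes, so how reads shared by a pair were assigned would bear on values for either.

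Several of these response and marker genes lie in clusters. In GRCh38 coordinates of GENCODE release 29, IFIT1, IFIT2 and IFIT3 lie on chromosome 10 between 89283694 and 89406486. The chemokine genes CXCL1, CXCL2, CXCL3, CXCL8, PF4 and PPBP lie on chromosome 4 between 73740506 and 74099293. The metallothionein genes MT1E, MT1F, MT1G, MT1M, MT1X and MT2A lie on chromosome 16 between 56608199 and 56684196. The HLA class II genes HLA-DRA, HLA-DRB1, HLA-DPA1, HLA-DPB1, HLA-DQA1 and HLA-DQB1, which encode chains that present antigen to CD4 T cells, lie on chromosome 6 between 32439842 and 33087201.

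Gene names had limits that bear on any reading of the list. For 12962 genes (33.6%) the identifier stood in place of a symbol. A further 21 symbols were each carried by more than 1 identifier, 43 identifiers in all, and none of these belonged to the response or marker lists.

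The third comparison concerned whether the libraries were separate at the level of barcodes. Of the barcode sequences, 156 occurred in both libraries (exact 95% Poisson interval 132 to 182), which was 0.633% of the developed-device list and 0.645% of the clinical-device list. The number expected by chance was 809 for the smallest barcode pool considered, 162 for the intermediate one and 87.8 for the largest. Only the intermediate expectation lay inside the interval of the observed number. Read the other way, the overlap gave a pool of 3825623 sequences (3270277 to 4504791).

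**Figure D1:**
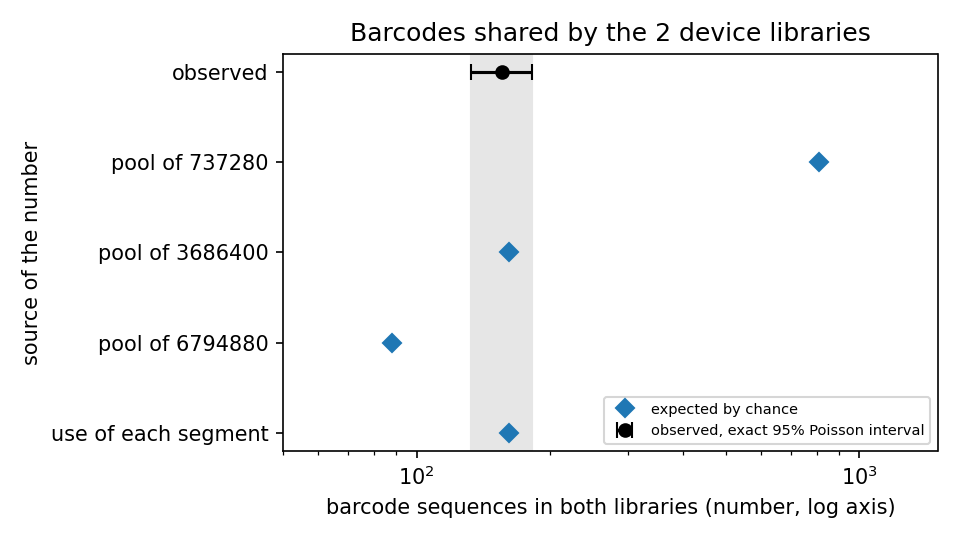
Number of barcode sequences found in both libraries (horizontal log axis) as observed, with its exact 95% Poisson interval as a bar and grey band, and the number that chance gives for 3 pool sizes and from the use of each 8-base barcode segment (blue diamonds). The intermediate pool (162) and the segment-based expectation (162) fall inside the interval of 132 to 182, and the expectations of 809 and 87.8 fall outside it.

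Both lists shared the same barcode architecture. The base at position 8, counted from 1 at the start of the barcode as written, fixed the base at position 9 in every barcode of both libraries, as AG, CA, GT or TC. Across both libraries, 3839 different sequences of the first 8 bases and 3838 of the last 8 bases were seen, and the combinations allowed by a common junction came to 3683520. No pair of barcodes within a library differed at a single base, in either library. Random joins of the observed 8-base segments held no such pair either, in 20 of 20 lists per device. The segments in use were therefore enough to give this absence. Base shares by position ranged from 17.3% to 30.5%. The largest of 64 differences between the libraries was 1.07 percentage points, for T at position 8 (and C at position 9, which it fixes). Its share was 26.2% (exact 95% binomial interval 25.7% to 26.8%) in the developed-device library and 25.2% (24.6% to 25.7%) in the clinical-device library. These intervals overlapped slightly and were not adjusted for picking the largest difference. Overlap of separate intervals does not show that the shares agree, and no interval of the difference was computed.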

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

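Of 15 alternatives run, 12 stayed within counting error, the spread between random lists or, for the number of genes, 1.5 times the main value. Several could not move, since all barcodes were already unique and 0 pairs at distance 1 left none to remove. Limits were wide for dropping shared barcodes and counting by symbol, so this tally does not show robustness. Without the shared barcodes, 24503 barcodes remained with the developed device and 24046 with the clinical device. Counting by symbol gave 38584 genes instead of 38606. Matching barcodes at up to 1 mismatch again gave 156. This setting had little room to move, since random joins of the 8-base segments within each library held no pair at distance 1. The other 3 moved. Reverse-complementing the developed-device list, meant to give a chance overlap, gave 0 shared barcodes, because the junctions AG, CA, GT and TC reversed give CT, TG, AC and GA, which no barcode has, so it is no chance value here. Random lists with the observed base shares at each position held on average 4.25 pairs at distance 1 for the developed device and 4.5 for the clinical device, against 0 and 0 when the observed first and last 8-base segments were joined at random, a setting chosen after seeing the data. Lists with the observed base shares ranged from 1 to 11 and from 2 to 7 pairs, so 0 of 20 had no pair for either device. Uniform base shares gave 2.4 (0 to 5, with no pair in 2 of 20 lists) and 3.55 (1 to 8, with no pair in 0 of 20), and joined segments gave no pair in 20 of 20 lists for both devices. The 8 alternatives planned for cell composition, expression and gene lists by cell class were not run, since expression values were not analysed here. With 1 library per device, no library could be left out, and the depth per cell is unknown.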

Other observations

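The comparison of the overlap with fixed pool sizes was planned before the data were examined, but the bound used to judge it and the segment-based test were chosen after the overlap was seen. The test of barcode use was set before its result. The 156 barcodes in both libraries could come from chance reuse of one pool, or from barcodes carried over between the libraries. Chance alone predicted 161.9 for the intermediate pool size, and 161.6 from the use of each 8-base barcode segment, both inside the interval of 132 to 182. The intermediate pool was singled out after the overlap was seen, so its match alone does not favour chance over carry-over. The segment-based number did not use the overlap. It is not independent of that pool size, since the segment combinations came to 3683520. At the upper end of the interval of 132 to 182, at most 20.9 barcodes exceeded the segment-based number, which is 0.0865% of the clinical-device list. If segments join at random as assumed, carry-over did not account for most of the overlap. A smaller amount of carry-over, and carried-over molecules in droplets left out of the lists, stay open.

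An uneven barcode pool common to both libraries was a candidate explanation for any spread in how often each first 8-base segment was used. The correlation of the counts per first segment between the libraries, within classes of the junction at positions 8 and 9, was smaller than the limit of 0.05 set beforehand (Pearson r = -0.020, permutation p = 0.23, Spearman rho = -0.023, permutation p = 0.148, both two-sided, 1 pair of lists, across 3839 segments that are not replicates of a culture). Within these classes, the variance of the counts was 1.01 times their mean with the developed device and 0.979 times with the clinical device. Both ratios were close to what counting error alone gives, so within the classes there was little spread to explain. The correlation therefore could not test the explanation. Neither ratio bears on use between the classes. The junctions AG, CA, GT and TC had 6046, 6174, 5968 and 6471 barcodes with the developed device. That range was wider than with the clinical device, at 6020, 6060, 6031 and 6091. No test across all 4 classes was made. For TC, the share with the developed device was 26.2% (exact 95% binomial interval 25.7% to 26.8%). That interval lay wholly above an even share among the 4 classes, so TC was used more than evenly in this list. With the clinical device the share was 25.2% (24.6% to 25.7%), and the interval held the even share. TC was picked as the largest class, and the intervals were not adjusted for this. No biological explanation was tested for any of these patterns.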
